A study of Mus musculus with 8 samples.

How the data were processed

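Messenger RNA was measured by sequencing in the ventral midbrain of 4 Ercc1 delta/+ and 4 wild type mouse samples. Per the labels' protocols, poly(A) RNA was selected, fragmented by heat, copied with oligo-dT and random primers, and barcoded, and the pooled libraries shared 1 sequencing lane; only RNA above a quality threshold was used. Per the submitters' processing notes, reads were handled with TopHat 1.3.1 and edgeR on the mm9 build. The tool that counted reads, its treatment of reads that fit several places and its treatment of strand are not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain.

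The authors deposited a table of 19931 rows, each a coding RefSeq transcript, with raw counts for the 8 samples, which are whole numbers with a different total per sample. The deposited log2 fold changes are the authors' own comparison of mutant with wild type for each row, made with edgeR per the submitters' processing notes, and a p-value and an adjusted p accompany them. The authors' adjusted p-values were recomputed from their deposited p-values by the Benjamini-Hochberg method over all rows and matched within 8.61e-08. The lowest total of a row over the 8 libraries is 31 counts, so rows of low count had been left out before. The design was written for counts, and the table holds counts.

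Rows were matched to gene symbols through a RefSeq table of the assembly GRCm38.p6 and a GENCODE M21 table: 19600 rows matched, and 331 without a match were kept by identifier. Because these references differ from mm9, they served only for names, transcript length, GC content and gene order, and no coordinates are given. For the 2906 genes with more than 1 row, the row with the highest total over the 8 libraries stood for the gene, and 45 genes with counts identical to another gene in all 8 libraries were merged with it, which left 15274 genes. Length and GC content were found for 97.99% of them. Counts of replicates differed beyond sampling noise in every pair of a group (lowest chi-square over degrees of freedom 11.9), so no library was counted as a copy of another. Totals after this step ran from 18268373 to 31197522 counts per library. At these depths 3 counts correspond to between 0.0962 and 0.164 CPM, and this limit covers counting error only.

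Before the data were examined, the groups, main tests, alternatives, gene lists and the rule for naming genes were fixed. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM normalization, filterByExpr on the 2 groups (14989 genes kept), robust=FALSE and Benjamini-Hochberg adjustment with a threshold of 0.05; tests were two-sided. Standard errors of log2 fold changes are the size of the estimate divided by the root of the F statistic. CPM values are normalised by TMM, with a prior count of 2 wherever log2 CPM is used. Of the gene lists, 36 with at least 5 tested members were tested by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. Beside it stand camera with an estimated correlation, fry, and an exact permutation test of the list mean over all assignments of 4 and 4 libraries. The mitochondrially encoded list had 0 genes in the table and the Y-linked list had 4, so neither was tested. List members were also adjusted over the list alone. The permutation test, this adjustment and the random lists matched on length and expression, used below, were not part of the plan fixed beforehand.

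Genes were named by this rule: Ercc1; per direction the 12 with the largest absolute log2 fold change among those past the threshold with no overlap between groups and a mean of at least 1 CPM, filled to 8 by smallest p, and said to have missed the threshold, where fewer than 5 qualified; up to 4 members per list with the smallest p; and Th, Slc6a3, Slc18a2, Ddc, Nr4a2, Pitx3, Cdkn1a, Gfap and Aif1 whatever their values. Not every gene the rule takes is named, and some are not reported here. Alternatives were RLE and upper-quartile scaling, no filter and a stricter filter, the edgeR exact test, DESeq2 1.42.0, limma-voom, robust=TRUE, the replicate number as a block, 1 surrogate variable (sva 3.50.0), leaving out each library, and, for lists, lists without shared members. Added after seeing the data were every transcript as its own row, an offset for transcript length and GC content (lowess with a span of 0.3 per library, fitted on genes with a mean log2 CPM above 2), the mean of 10 choroid plexus genes as a covariate, and a term for the 4 libraries of lowest total.

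The tests were tried on simulated data with the means, dispersions and library sizes of this comparison and a set of changed genes. In that simulation of Ercc1 delta/+ against wild type over 14924 genes, the quasi-likelihood test recovered 83% of 100 genes changed 2-fold and 41% of 100 changed 1.5-fold, with 7.46% of its calls false. The edgeR exact test and DESeq2 recovered 94% and 93% of the 2-fold changes with 22.2% and 23.1% of calls false, and limma-voom 82% with 6.77% false. With no simulated effect camera called 0 lists, and with 1 list shifted by 0.3 on the log2 scale it called 1; the simulated genes vary independently, unlike those of a tissue.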

Results

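RNA was sequenced from the ventral midbrain of mice, the region that holds the dopaminergic neurons lost in Parkinson disease. There were 4 samples from Ercc1 delta/+ mice, which carry 1 mutant allele of a DNA repair gene, and 4 from wild type mice. With 1 row kept per gene, the mutant libraries held 22187746, 18268373, 27146604 and 21883216 counts for replicates 1 to 4, and the wild type libraries held 25886618, 20517887, 25027460 and 31197522 counts. The 10 most abundant genes took between 3.16% and 3.86% of the counts of a library. The labels do not say that each sample is a separate animal, so p-values measure the spread between these samples, which may in part be technical.

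The first comparison checked the targeted gene. Ercc1 (RefSeq NM_007948) encodes a subunit of the endonuclease that cuts out damaged DNA in nucleotide excision repair. Its normalised expression, in counts scaled to library size (CPM), was 11.5 ± 1.17 CPM (SD, n = 4) in Ercc1 delta/+ and 14.6 ± 0.724 CPM (SD, n = 4) in wild type. The mutant replicates 1 to 4 held 10.2, 12.9, 11.1 and 11.9 CPM, and the wild type replicates 14.1, 15.4, 15.0 and 13.8 CPM, so the groups did not overlap and each library stood on the side its label gives. The log2 fold change of Ercc1 was -0.34 (SE 0.10), or 0.792 times the wild type level, and it did not pass the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment (adjusted p = 0.114). With DESeq2 the adjusted p was 0.0391, and across all alternatives it ran from 0.0391 to 0.425. Which part of the transcript the delta allele leaves is not given in the labels, so the expected size of the difference is unknown.

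Over all genes, the comparison asked which transcripts differ in midbrain when 1 allele of this repair gene is mutant. Of 14989 genes tested, 7 passed an adjusted p of 0.05 by the edgeR quasi-likelihood test, 2 higher and 5 lower in Ercc1 delta/+, and in each of the 7 the groups did not overlap. Zbtb16, a zinc finger transcription factor gene induced by glucocorticoids, rose from 14.2 ± 4.43 to 66.5 ± 15.1 CPM (SD, n = 4 each), a log2 fold change of 2.23 (SE 0.24, adjusted p = 0.0341). Myh9, which encodes a non-muscle myosin heavy chain, rose by 0.55 on the log2 scale (SE 0.07, adjusted p = 0.0389). Rpl17 and Rpl7a, which encode proteins of the large ribosomal subunit, had log2 fold changes of -1.85 (SE 0.15, adjusted p = 0.00591) and -1.47 (SE 0.18, adjusted p = 0.0389). Rpl17 stood at 4.37 ± 0.911 CPM against 15.8 ± 1.03 CPM in wild type (SD, n = 4 each). The predicted gene Gm12657 had a log2 fold change of -0.88, the histone gene H3f3a -0.60 and Fundc2, a mitochondrial outer membrane protein gene, -0.59. Rpl17, Rpl7a and H3f3a have near-identical copies in the genome, and how shared reads were counted is not given, so their values are uncertain.

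**Figure D1:**
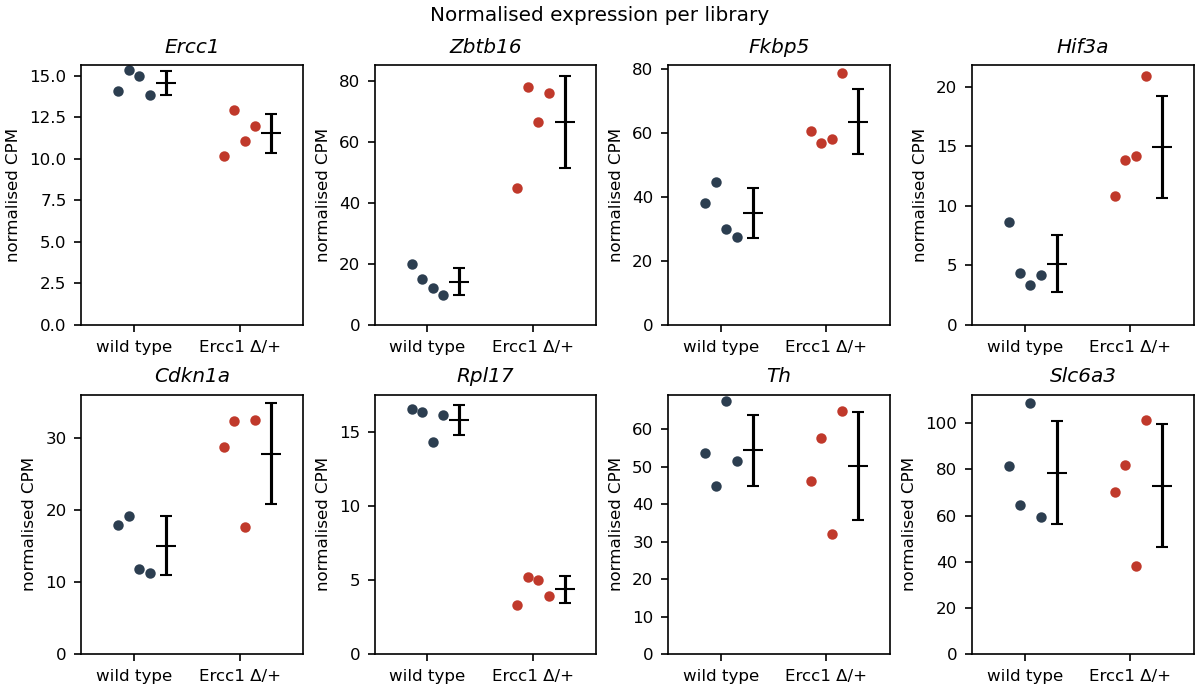
Normalised expression in CPM (linear axis from 0) of 8 genes in each of the 8 libraries. Points are libraries in replicate order, and the bar beside them is the mean with the SD (n = 4 per group); Ercc1, Zbtb16, Fkbp5, Hif3a and Rpl17 show no overlap between the groups, while Th, Slc6a3 and Cdkn1a do overlap.

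Many more genes lay just short of the threshold. There were 92 genes with an adjusted p between 0.05 and 0.06, 36 higher and 56 lower, and 570 genes below 0.1. In the higher direction the smallest p-values short of the threshold belonged to Arhgap31 (log2 fold change 0.64), Lyst (0.49), Aff1 (0.76), Setbp1 (0.52), Rin3 (1.01) and Arhgap39 (0.49), each with an adjusted p of 0.0503, and these missed it. At an unadjusted p of 0.05, 2789 genes (18.6%) stood out, and 1803 genes (12.03%) had groups that did not overlap. Chance gives 2.86% on average over all assignments of 4 and 4 libraries. Because genes vary together, a single split can lie far from that average, and the share in other splits was not computed. The count of 7 depended on the tool and on single libraries. It was 52 with limma-voom, 538 with the edgeR exact test and 1024 with DESeq2, and it was 0 without Ercc1 delta/+ replicate 4, 3 without replicate 1, 1 without replicate 3 and 321 without replicate 2. It was 2 without wild type replicate 1 and 1 without wild type replicate 2, 3 or 4.

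The libraries also differed in depth in a way that overlaps with genotype. The 4 libraries with the lowest totals were Ercc1 delta/+ replicates 1, 2 and 4 and wild type replicate 2. Each depth group thus holds a single library of 1 genotype, too few for a comparison within it. With the depth group as a term in the fit, 1 gene passed, in the lower direction. Of 36 gene lists 16 were called, against 17 without the term, and only 13 were called both ways. The nucleotide excision repair, heat shock, hypothalamic and cortical lists lost their call. The microglia, astrocyte and dopamine signalling lists were called lower only with the term.

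Lists of the protein synthesis and respiratory machinery were called lower in Ercc1 delta/+ by camera, and for the respiratory lists the groups overlapped. All 46 cytosolic ribosomal protein genes on the list had a negative log2 fold change, with a median of -0.42, and 42 of them passed the quasi-likelihood test adjusted over the list alone, against 0 over all genes tested. Rps14 had a log2 fold change of -0.63 (SE 0.10), Rpl15 -0.41 (SE 0.07), Rpl3 -0.38 (SE 0.06) and Rps9 -0.39 (SE 0.07). The list mean of every mutant library lay below that of every wild type library (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give, 0.171 after adjustment over 36 lists). By camera with a preset correlation its adjusted p was 3.91e-36, and the adjusted p was 0.437 with an estimated correlation.

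All 37 subunit genes of respiratory complex I and all 39 of complexes II to V, which carry electron transport and ATP synthesis in mitochondria, also had negative log2 fold changes, with medians of -0.31 and -0.31. Adjusted over the list alone, 17 and 18 of them were lower, and 0 in either list passed over all genes tested. Ndufb2 (-0.59) and Ndufa7 (-0.70) of complex I and Cox7c (-0.54) and Uqcrfs1 (-0.31) of the other complexes had the smallest or near-smallest p-values. Camera gave adjusted p-values of 2.87e-16 and 1.53e-15, and the adjusted p was 0.474 for both lists with an estimated correlation. In Ercc1 delta/+ replicate 2 the mean of complex I lay at 0.12 above the mean of the 8 libraries, inside the wild type range of 0.06 to 0.22, and for each list the exact permutation p was 0.0571 and the fry adjusted p 0.114.

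These lists moved together with transcript length. Across genes, which are not independent replicates, the log2 fold change correlated with transcript length at a Spearman coefficient of 0.395 and with GC content at 0.204. The shortest 10% of transcripts had a median log2 fold change of -0.21 and the longest 10% of 0.14. The ribosomal protein genes have a median transcript length of 834 bases, against 3006.5 for all genes. With an offset for the trend over length and GC, chosen after seeing the data, the coefficient with length was 0.0768, so the trend was reduced but not gone. The median of the ribosomal protein list was then -0.21, of complex I -0.07 and of complexes II to V -0.09, and the count of genes past the threshold fell to 1.

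**Figure D2:**
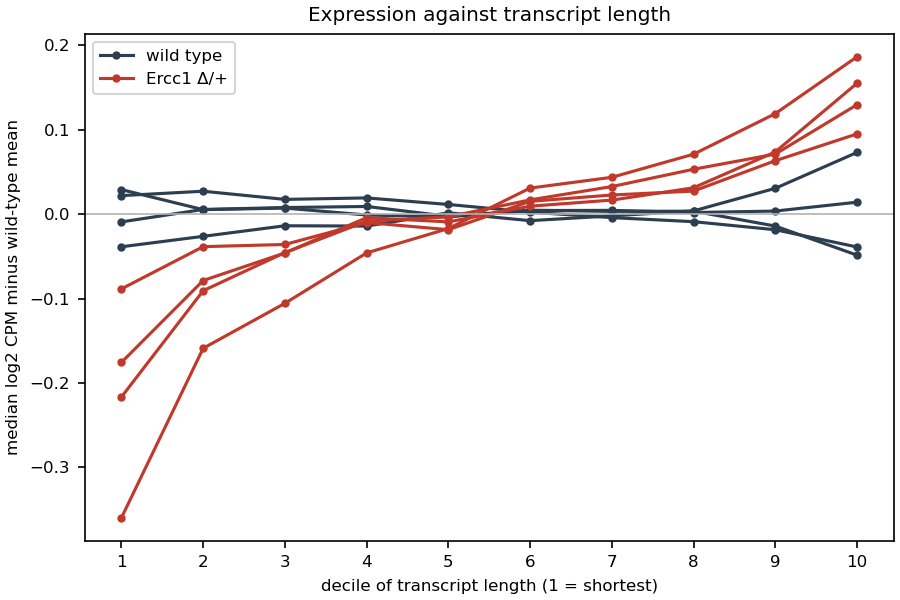
Median over genes of log2 CPM minus the wild type mean (y axis) in each decile of transcript length (x axis, 1 is the shortest), with a line for each of the 8 libraries. The baseline centres the wild type lines near 0 as a group, but single ones still varied with length. Wild type replicates 1 to 4 stood at -0.01, 0.03, 0.02 and -0.04 in the shortest decile. In the longest they stood at 0.01, -0.05, -0.04 and 0.07. All 4 Ercc1 delta/+ lines run from negative values in the shortest decile (-0.36 to -0.09) to positive values in the longest (0.10 to 0.19).

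Glucocorticoid-induced genes were higher in Ercc1 delta/+. All 15 genes of this list had a positive log2 fold change, with a median of 0.73, or 1.66-fold, and 10 were higher adjusted over the list alone. Zbtb16 alone passed over all genes tested. Fkbp5, which encodes a chaperone that restrains the glucocorticoid receptor, stood at 63.5 ± 10.1 CPM in mutants and 34.9 ± 7.90 CPM in wild type (SD, n = 4 each), and its log2 fold change of 0.86 (SE 0.17) had an adjusted p of 0.0619. Hif3a (1.54, SE 0.31) and the phagocytic receptor gene Mertk (1.02, SE 0.17) had adjusted p-values of 0.0639 and 0.0520. The list mean was above every wild type library in all 4 mutant libraries (exact two-sided permutation p = 0.0286, adjusted 0.171). Camera gave an adjusted p of 9.09e-15, and it was 0.302 with an estimated correlation.

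Immediate early genes, transcribed within minutes of neuronal or stress signals, were also higher as a list (camera adjusted p = 2.21e-06, adjusted p = 0.474 with an estimated correlation). Of its 22 genes 18 were positive and 7 were higher adjusted over the list alone, with 0 over all genes tested. Fosb (1.03), Fosl2 (0.99), Klf4 (0.67) and Per1 (0.44) were among the 7. Ercc1 delta/+ replicate 3 did not share this, with a list mean of -0.37. The heat shock and unfolded protein response list was called higher (camera adjusted p = 0.000175, adjusted p = 0.474 with an estimated correlation), with 27 of 31 genes positive and 0 passing in either adjustment. With the depth term its adjusted p was 0.229. Mutant replicate 3 (list mean -0.18) lay below wild type replicates 1 (0.02) and 2 (0.06). The exact two-sided permutation p was 0.114 for this list and for the immediate early list. Hspa1a and Hspa1b, near-identical chaperone genes that share reads, had log2 fold changes of 2.34 (SE 0.61) and 2.35 (SE 0.62), Hspb1 1.31 and Dnajb1 0.63. Hspa1a reached 419 CPM in Ercc1 delta/+ replicate 4 and 186 CPM in replicate 1, against 49.6 CPM in replicate 3.

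**Figure D3:**
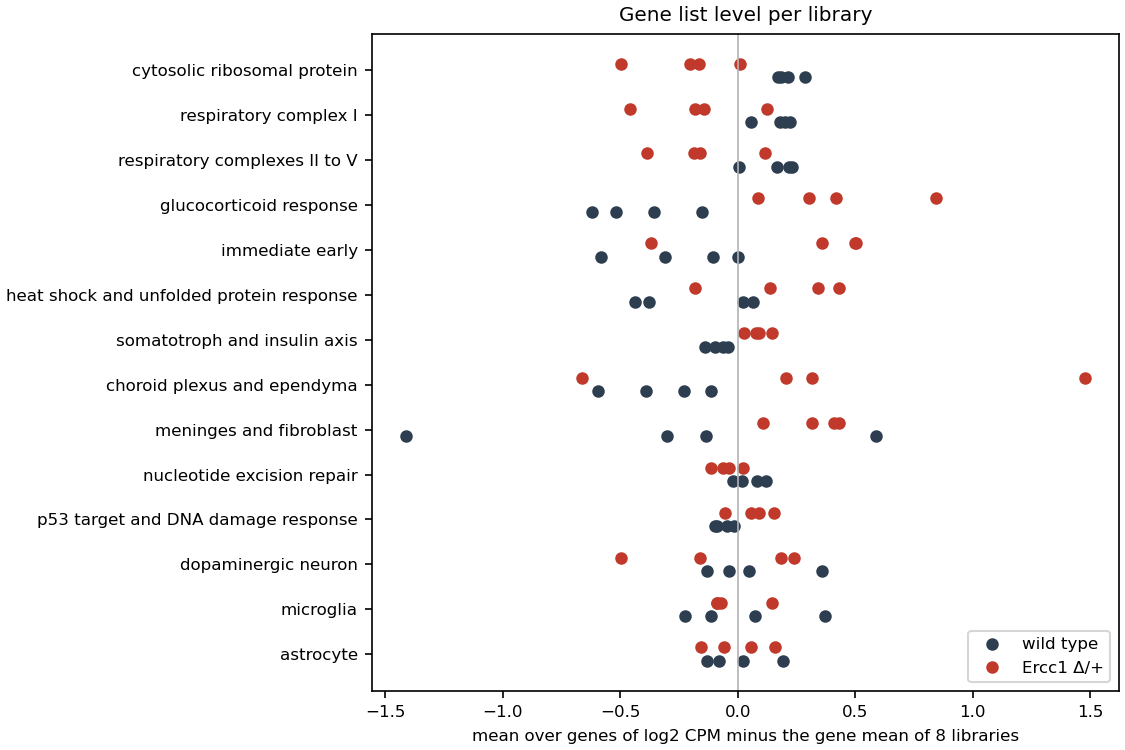
Mean over the genes of a list of log2 CPM minus the gene's mean over the 8 libraries (x axis) for 14 gene lists (y axis), with 1 point per library. Ribosomal protein, glucocorticoid and insulin axis lists separate the 4 mutant from the 4 wild type libraries, the dopaminergic neuron, microglia and astrocyte lists overlap, and 1 mutant library stands far to the right for choroid plexus (replicate 3, at 1.48).

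For the dopaminergic neurons themselves no difference passed the test. Of 24 marker genes 6 had a positive and 18 a negative log2 fold change, 0 passed adjusted over the list alone, and the list was not called (median -0.10, camera adjusted p = 0.357). Th, the rate-limiting enzyme of dopamine synthesis, stood at 50.2 ± 14.4 CPM in mutants and 54.4 ± 9.50 CPM in wild type (SD, n = 4 each), a log2 fold change of -0.12 (SE 0.21). The dopamine transporter gene Slc6a3 had a value of -0.11 (SE 0.29), the vesicular transporter gene Slc18a2 -0.30 (SE 0.22), Ddc -0.33 (SE 0.22), the transcription factor genes Nr4a2 0.50 (SE 0.24) and Pitx3 -0.03 (SE 0.43). Ercc1 delta/+ replicate 3 held the lowest dopaminergic list mean (-0.50), and without it the log2 fold changes of Th and Slc6a3 were 0.05 and 0.11. The dopamine signalling and metabolism list (20 genes, median -0.03, camera adjusted p = 0.163) had 0 genes past the test, and it was called lower with the depth term (adjusted p = 0.0223) and with 1 surrogate variable (0.0481).

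Of 22 genes linked to familial Parkinson disease, 0 passed adjusted over the list alone and the list was not called by camera (median 0.07, adjusted p = 0.335). Groups did not overlap for 5 higher genes and 1 lower gene of the list, where 12.03% of all genes tested did not overlap. Among them were Eif4g1 (0.21, SE 0.05), Gigyf2 (0.20, SE 0.06) and Uchl1 (-0.22, SE 0.07). With the length and GC offset the list median was 0.05 and the camera adjusted p 0.469. The list means of the mutant libraries lay above those of the wild type libraries by a small margin (mean log2 fold change 0.05, exact two-sided permutation p = 0.0286, adjusted 0.171). Presynaptic genes were higher as a list (27 of 28 positive, median 0.11, camera adjusted p = 0.000515, adjusted p = 0.474 with an estimated correlation). The groups overlapped, as mutant replicate 3 (list mean -0.07) lay below wild type replicates 1, 2 and 3 (-0.04, -0.02 and -0.06). The exact two-sided permutation p was 0.114. Sv2c (0.47), Unc13a (0.33) and Bsn (0.57), which encode a vesicle protein and scaffolds of the release site, were higher adjusted over the list alone, and 0 over all genes tested. With the length and GC offset 0 presynaptic genes passed, while 25 of 28 were positive, the median was 0.09 and the list was called (adjusted p = 0.0202); of random lists matched on length and expression, 95% had a median between -0.01 and 0.11, a range that holds the 0.108 of this list. Means of the cortical, hippocampal and thalamic neuron list were 0.52, 0.61 and -0.21 in mutant replicates 1, 2 and 3 and -0.82 in wild type replicate 4, where those of the presynaptic list were 0.16, 0.23, -0.07 and -0.23.

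Nucleotide excision repair genes were called lower by a narrow margin (24 of 34 negative, median -0.09, camera adjusted p = 0.0490, adjusted p = 0.474 with an estimated correlation), with 0 genes passing in either adjustment. Ercc1, the targeted gene, is itself among the 34 and had the smallest p. The list was not tested without it, so the call does not speak for the other members alone. Ercc8 (-0.29) and Mnat1 (-0.33) were negative and Ercc6 (0.29) positive. The call was kept in 5 of 18 other settings. It was lost without mutant replicate 1 (adjusted p = 0.121), 2 (0.0836) or 4 (0.0595), without wild type replicate 3 (0.0658) or 4 (0.118), with RLE scaling (0.0553), the stricter filter (0.0512), the replicate block (0.0522), 1 surrogate variable (0.110), lists without shared members (0.0610), the length and GC offset (0.152), the choroid plexus covariate (0.0527) and the depth term (0.203). Other DNA repair genes (36 tested, median -0.09, adjusted p = 0.357) and p53 target genes (30 tested, 21 positive, median 0.06, adjusted p = 0.120) were not called, and 0 genes of either passed. Cdkn1a, the p53-induced cell cycle inhibitor gene that glucocorticoids also induce, stood at 27.8 ± 6.99 CPM against 15.0 ± 4.10 CPM (SD, n = 4 each), with a log2 fold change of 0.89 (SE 0.24, adjusted p = 0.103). Sesn2 had a value of 0.25. Without mutant replicate 3 the p53 list was called by camera (adjusted p = 0.0401), as it was with the length and GC offset (adjusted p = 0.0186) and the choroid plexus covariate (0.00463).

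Senescence and secretory genes were not called by camera (12 tested, median 0.26, adjusted p = 0.216), although 3 were higher adjusted over the list alone, among them Igfbp7 (0.30) and Cdkn1a, and fry gave an adjusted p of 0.0493. Without members shared with other lists, such as Cdkn1a, 9 genes were tested and the camera adjusted p was 0.680. In the somatotroph and insulin axis, 15 of 20 genes were positive (median 0.13, camera adjusted p = 0.000400, adjusted p = 0.195 with an estimated correlation). Adjusted over the list alone 6 were higher, and 0 passed over all genes tested. Among the 6 were the receptor gene Igf1r (0.31, SE 0.07) and the growth factor binding protein gene Igfbp2 (0.70, SE 0.16). Irs2 (0.36, SE 0.08) and Mtor (0.20, SE 0.06) were others. With the length and GC offset the list median was 0.04, 1 gene of the list passed and the list was called (adjusted p = 0.0385); of random lists matched on length and expression, 95% had a median between -0.03 and 0.15, a range that holds the 0.13 of this list. The list means of the 4 mutants exceeded those of the 4 wild type libraries (exact two-sided permutation p = 0.0286, adjusted 0.171). Antioxidant genes were called lower (21 of 30 negative, median -0.07, camera adjusted p = 0.0108, adjusted p = 0.474 with an estimated correlation). Prdx1 (-0.47), Txn1 (-0.47) and Gpx1 (-0.42), with transcripts shorter than the median, were lower adjusted over the list alone, and 0 over all genes tested. That call was lost without mutant replicate 1 (adjusted p = 0.0546) or 3 (0.0689), without wild type replicate 2 (0.117), with the length and GC offset (0.314) and with the choroid plexus covariate (0.0537). Mitochondrial biogenesis genes (31 tested, median -0.02, adjusted p = 0.239) were not called, and Fundc1 (-0.39), a mitophagy receptor gene, was lower adjusted over the list alone; the list mean of every mutant library lay below that of every wild type library (mean log2 fold change -0.06, exact two-sided permutation p = 0.0286, adjusted 0.171). Autophagy and lysosome genes (35 tested, median -0.02, adjusted p = 0.563) and cell cycle genes (24 tested, median 0.08, adjusted p = 0.287) were not called and held 0 genes past the test.

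Markers of mature glia did not pass the test. Astrocyte (20 genes, adjusted p = 0.797), microglia (21 genes, 0.649), oligodendrocyte (21 genes, 0.279) and inflammation and interferon lists (24 genes, 0.163) were not called by camera and held 0 genes past the test. Other settings did call them: astrocyte genes lower with the depth term (adjusted p = 0.0237), microglia genes lower with the depth term (0.00907) and 1 surrogate variable (0.0481), oligodendrocyte genes lower with 1 surrogate variable (0.0246), the choroid plexus covariate (0.0112) and without wild type replicate 4 (0.000435), and inflammation genes higher with the length and GC offset (0.0202) and without wild type replicate 4 (0.0368). Gfap had a log2 fold change of 0.15 (SE 0.13) and Aif1 of -0.22 (SE 0.16). Oligodendrocyte precursor genes were called higher (11 of 13 positive, median 0.17, camera adjusted p = 0.0144, adjusted p = 0.474 with an estimated correlation). Adjusted over the list alone, Tnr (0.40) and Vcan (0.27) were among 4 that were higher and Lhfpl3 (-0.31) was the 1 that was lower, with 0 over all genes tested; the list means of the mutants exceeded those of the wild type libraries (exact two-sided permutation p = 0.0286, adjusted 0.171). The call was lost without mutant replicate 1 (adjusted p = 0.0546) or 3 (0.05996), with the choroid plexus covariate (0.0535) and with the length and GC offset (0.298), where the median was 0.07.

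Vessel, meningeal and choroid plexus markers were called higher and blood markers lower by camera, while the exact two-sided permutation p of their list means was 0.143, 0.171, 0.2 and 0.0571. Endothelium and pericyte genes (19 of 23 positive, median 0.21, camera adjusted p = 0.000257) had 3 genes higher adjusted over the list alone, the glucose transporter gene Slc2a1 (0.58, SE 0.09), Flt1 (0.43) and Adgrl4 (0.49). Meningeal genes (15 of 15 positive, median 0.42, camera adjusted p = 0.000151) had 0, with Col1a1 at 0.52 and Igf2 at 0.81, and wild type replicate 1 lay far below the rest (list mean -1.41) while wild type replicate 4 had the highest mean of the 8 libraries (0.59). Choroid plexus and ependyma genes (12 of 16 positive, median 1.26, camera adjusted p = 0.00442) had 6 higher adjusted over the list alone, among them Kcnj13 (1.76), Kl (1.64), F5 (1.81) and Slc4a5 (2.16). Kl stood at 56.5 CPM in mutant replicate 3, 29.1 and 30.4 CPM in replicates 1 and 2, and 11.7 CPM in replicate 4, against 9.58 to 11.4 CPM in wild type. Without mutant replicate 3 the plexus list was not called (adjusted p = 0.172). Of the 5 blood genes 4 were negative (median -0.25, camera adjusted p = 0.00486), and Hbb-b2 (-0.79) and Hba-a1 (-0.45), globin genes whose counts cannot be told apart from those of a paralog, were lower adjusted over the list alone; the call was lost without mutant replicate 3 (adjusted p = 0.0689) and with the choroid plexus covariate (0.0537). For these 4 lists the adjusted p was 0.474 with an estimated correlation, and 0 of their genes passed over all genes tested.

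Genes neighbouring Ercc1, which may travel with the targeted allele in a mixed FVB and C57BL/6J background, were not called as a list (53 tested, 30 positive, camera adjusted p = 0.281). Camera asks for a shared direction, so it cannot exclude linked differences in both directions. Groups did not overlap for 3 higher and 3 lower genes of the list, where 12.03% of all genes tested did not overlap. By fry without regard to direction the unadjusted p was 0.000446. Hif3a was the 1 neighbour higher adjusted over the list alone, and it is also a member of the glucocorticoid list, while Fosb is a neighbour that the immediate early list also holds.

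The authors' deposited table gave 371 transcript rows past its adjusted p of 0.05, 203 higher and 168 lower in Ercc1 delta/+, which name 309 genes. All 7 genes called here were among them. Of the genes tested here, 295 had a row past the authors' threshold, while 371 counts transcript rows. Across the genes tested, the log2 fold changes in the authors' deposited table and those computed here had a Spearman coefficient of 0.995. Both come from the same deposited counts, so this likeness and the shared calls are no independent support.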

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

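In groups of 4 libraries, a library was picked out when its gap to the nearest other library as a share of the group's range passed Dixon's critical value for 4 samples. Of 230 groups examined, over the named genes and the gene lists, 15 met this, and chance alone gives about 5%. Most of the 15 may therefore be chance, and the groups are not independent because genes vary together. All of these shares were computed on log2 CPM or on list means of it.

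Ercc1 delta/+ replicate 1 was the low library for Ndufb2 (0.920 of the range), Ndufa7 (0.908), Rps9 (0.869) and the mitochondrial biogenesis list (0.865), and the high library for the microglia list (0.924). Ndufa7 stood at 17.1 CPM there, against 26.2 to 27.4 CPM in the other mutant libraries. Ercc1 delta/+ replicate 2 was the high library for Ercc8 (0.866) and the familial Parkinson disease list (0.893), and the low library for the hypothalamic and pituitary list (0.877), whose mean there was -2.26 against 0.04 to 0.36 in the other mutants. Ercc1 delta/+ replicate 3 was the low library for the immediate early list (0.837), with a mean of -0.37 against 0.36 to 0.50.

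Wild type replicate 2 was the high library for Rpl15 (0.963) and the low library for Lhfpl3 (0.951). Wild type replicate 3 was the low library for Setbp1 (0.892) and Rpl17 (0.833), the latter at 14.3 CPM against 16.1 to 16.5 CPM. Wild type replicate 4 was the low library for Uqcrfs1 (0.874), at 96.6 CPM against 112 to 115 CPM, and the high library for the Y-linked list (0.8294), whose means over all 8 libraries ran from -0.36 to 0.29.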

How the results depend on the processing

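The length and GC offset, the choroid plexus covariate, the depth term and the test of every transcript as a row were chosen after seeing the data. The cause of the changes below was not tested, except that leaving out a library leaves fewer samples. Against 7 genes (2 higher, 5 lower), the count was 33 with RLE scaling (12 and 21), 86 with upper-quartile scaling (22 and 64), 50 with the stricter filter, 538 with the edgeR exact test (238 and 300), 1024 with DESeq2 (496 and 528), 52 with limma-voom and 348 with 1 surrogate variable (159 and 189). It was 4 with every transcript as a row, 1 with the length and GC offset, 1 with the depth term and 0 with the choroid plexus covariate, where edgeR gave 1779 genes at an unadjusted p under 0.05. Leaving out single libraries gave 0 (without Ercc1 delta/+ replicate 4, 2101 at an unadjusted p under 0.05) to 321 genes (without Ercc1 delta/+ replicate 2, 74 higher and 247 lower). With no filter it was 7 and with robust=TRUE 9. All 7 genes were shared by the calls of the 9 other planned settings that keep every library and add no block.

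Replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.28, 0.17, -0.12 and 0.26, and not every sample correlated best with its own number. With the replicate block 0 genes passed by edgeR, 2928 had an unadjusted p under 0.05, and 16 lists were called. The log2 fold change of Ercc1 was negative in every setting, from -0.39 to -0.28, and passed the threshold only with DESeq2 (-0.33).

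Of 36 lists 17 were called. With an estimated correlation 0 were called and with fry 4, and other settings gave 13 to 17. The lists called by fry were the insulin axis (adjusted p = 0.0137) and the ribosomal protein, glucocorticoid response and senescence lists (0.0493 each). The offset called 15, the choroid plexus covariate 13 and the depth term 16, of which 13, 11 and 13 were among the 17. Robust=TRUE does not enter camera. The lists for ribosomal proteins, both respiratory lists, glucocorticoid response, immediate early, endothelium, meninges, presynaptic and insulin axis genes kept their call in all 18 settings other than those for the correlation and fry.

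Over 78 named genes and 1715 fits, 1439 kept direction and side of the threshold, 70 lost the call, 192 gained it and 14 turned direction, in 6 genes that had not passed. With the choroid plexus covariate the log2 fold changes were Th 0.23, Slc6a3 0.31, Pitx3 0.50 and Slc4a5 -0.17. With the depth term Gfap was -0.0201, with DESeq2 Pitx3 was 0.0011, and with the offset Aif1 was 0.0154. Leaving out single libraries, Th ran from -0.27 to 0.0486, Slc6a3 from -0.31 to 0.11 and Pitx3 from -0.42 to 0.31. Pitx3, with 138 counts over the 8 libraries, turned direction in 5 settings, and Th and Slc6a3 in 3 each. At these depths levels below 0.0962 to 0.164 CPM (3 counts) are not detectable.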

Other observations

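The tests of transcript length and GC, of the 4 libraries of lowest total, of clock phase and of covariation among plexus genes, and the choroid plexus covariate itself, were chosen only after the result was seen. What the thinning of libraries, the counts of splits and the covariate's effect on the glucocorticoid list would show was written down before their results were seen.

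Markers of brain regions beside the ventral midbrain varied from library to library in both genotypes. Hypothalamic and pituitary genes were called lower (12 of 14 negative, median -0.48, camera adjusted p = 0.00705, adjusted p = 0.474 with an estimated correlation), with Foxb1 (-1.01) lower adjusted over the list alone and the hypothalamic neuropeptide gene Pmch at -1.19. That call was lost without Ercc1 delta/+ replicate 2 (adjusted p = 0.229) or wild type replicate 4 (0.0760), where Pmch stood at 12.1 CPM and 274 CPM, and with 1 surrogate variable (0.122) and the depth term (0.0878). Cortical, hippocampal and thalamic neuron genes were called higher (13 of 20 positive, median 0.43, camera adjusted p = 0.0490, adjusted p = 0.474 with an estimated correlation) with 0 genes past the test, Nptx1 standing at 0.79. The call was kept in 7 of 18 other settings, and lost without mutant replicate 1 (adjusted p = 0.0883) or 2 (0.132), without wild type replicate 3 (0.0592) or 4 (0.197), with RLE scaling (0.0553), the stricter filter (0.0526), 1 surrogate variable (0.0667), lists without shared members (0.0503), the length and GC offset (0.152), the choroid plexus covariate (0.0973) and the depth term (0.222).

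Striatal neuron genes (14 tested, adjusted p = 0.734), serotonergic genes (6 tested, 0.994), hindbrain and cerebellar genes (9 tested, 0.671), red nucleus and oculomotor genes (9 tested, 0.279) and GABAergic genes (18 tested, 0.649) were not called by camera and held 0 genes past the test. Striatal list means were 1.02 in mutant replicate 1 and 1.24 in wild type replicate 2, against -1.01 in mutant replicate 2, and without wild type replicate 2 the striatal list was called higher (adjusted p = 0.00981). Serotonergic list means ran from -1.26 in mutant replicate 3 to 1.69 in mutant replicate 2. For the hindbrain list the median (-0.06) and the test pointed lower while the mean (0.30) was positive.

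The counts of calls themselves do not exclude chance. Among the 35 splits of the 8 libraries into 4 and 4, 2 gave at least 7 genes, the real split and another with 188 genes, and the remaining splits gave 0. Camera called at least 17 lists in 4 of the 35 splits, with 18 as the highest of the other splits and a median of 14, so a camera call with the preset correlation says little by itself in these libraries. The split with 188 genes sets the 4 libraries of lowest total against the 4 of highest total, and 3 of the 4 lowest are mutant. It points to a structure of the samples other than genotype; on the first principal component, with 37.6% of the variance, these 4 libraries had negative and the other 4 positive scores. With the depth term 1 gene passed for genotype.

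Ribosomal protein and respiratory chain lists were called lower in Ercc1 delta/+ by camera with the preset correlation. With an estimated correlation they were not (adjusted p = 0.437 for the ribosomal list and 0.474 for each respiratory list). The shortest 10% of transcripts had a median of -0.21. For the respiratory lists mutant replicate 2 (0.12 for each) lay inside the wild type range and the exact permutation p was 0.0571. The offset for transcript length and GC, which left a Spearman coefficient of 0.0768 with length, brought the median log2 fold change of the ribosomal protein list from -0.42 to -0.21 (SE 0.04), which argues against that trend as the whole cause, and that of the respiratory chain genes from -0.31 to -0.0749 (SE 0.05). Random lists matched on length and expression had a median of -0.23 (95% of them between -0.29 and -0.18) for the ribosomal list. For the respiratory genes it was -0.22 (between -0.27 and -0.17), and each real median before the offset lay below its range. Genes of random lists need not vary together, so these ranges may be too narrow to decide. The estimated correlation was 0.72 within the ribosomal list, 0.84 within complex I and 0.82 within complexes II to V. With the offset, camera at the preset correlation of 0.01 called complex I (adjusted p = 2.60e-05) and complexes II to V (2.80e-05), which decides little for the same reason. Whether the trend is the whole cause for the respiratory genes stays open. With the depth term, which divides the 4 libraries of lowest total from the rest, the median of the ribosomal list was -0.45 (SE 0.15). Each depth group holds a single library of 1 genotype, too few to argue for or against that division as the cause. Thinning all libraries to the smallest total left -0.42 (SE 0.12) but moved 0 of 46 ribosomal genes by more than their standard error. Thinning therefore decides nothing on depth. What produced the length trend stays open, since differences in RNA integrity or library preparation, reads shared with the pseudogenes of ribosomal proteins, and the genotype itself were not tested.

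The glucocorticoid response list was higher in all 4 mutants. Its median log2 fold change stayed at 0.78 (SE 0.18) with the length and GC offset and was 1.00 (SE 0.20) with the choroid plexus score as a covariate, which argues against both as the whole cause. Another phase of the daily clock may raise the same genes: the difference between 7 clock output genes and Arntl, Npas2 and Clock was -0.0574 (SE 0.30, exact two-sided permutation p = 0.857), too wide a spread to decide. Handling stress and time of death are not given in the labels, and the genotype remains an open and untested explanation.

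Choroid plexus epithelium genes, Clic6 apart, were highest in Ercc1 delta/+ replicate 3, intermediate in replicates 1 and 2 and near wild type in replicate 4. Ttr, the most abundant of them and named after its values were seen, stood at 993, 283, 411 and 32.5 CPM in mutant replicates 3, 1, 2 and 4, and at 18.3 to 112 CPM in wild type. Clic6, also named after its values were seen, stood at 9.92 CPM in mutant replicate 2, below the 16.5 to 23.7 CPM of wild type. Within groups the 10 plexus epithelium genes varied together (mean pairwise correlation 0.775, where 95% of random sets lay below 0.147), which is consistent with different amounts of plexus tissue in the samples; 8 of the 10 reached a mean of 1 CPM in wild type, and 0 belong to another list. The length and GC offset left their median at 1.91 (SE 0.69), which argues against that trend as the cause. A difference in plexus size or activity between genotypes was not tested.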
